A study of Mus musculus with 12 samples.

How the data were processed

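The series measured poly-A RNA of mouse bone marrow-derived macrophages by RNA sequencing. Per the labels' protocols, marrow cells of 8-week-old male mice were cultured with 50 ng/mL M-CSF, the growth factor that drives marrow precursors towards macrophages. The mice had 1 of 2 genotypes that the labels call Itga9-Lyz2-cHet and Itga9-Lyz2-cKO, shortened here to cHet and cKO. Cultures were left untreated (control) or were stimulated with an agent that the labels call Pg at a multiplicity of infection of 1:20 for 2 hours. Each of the 4 groups held 3 libraries, 12 in all, named here by group and replicate number. The labels do not say whether the libraries of a group came from separate mice or cultures, so every p-value measures the spread between these libraries, which may be technical.

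The authors deposited raw read counts per gene, in 1 table with a column for each library. Per the submitters' processing notes, fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used with genome build mm10. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping, antisense or near-identical genes can therefore be assigned to the wrong partner. Fragments of 370 to 420 bp were selected per the labels' protocols. The deposited table gives gene positions in mm10 beside the counts. Of its 54532 gene identifiers, 54409 (99.8%) were found in the mm10 reference annotation used here, and 53499 of these (98.3%) had the same start and end.

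Library totals lay between 14527674 counts (cKO control 2) and 16793803 counts (cHet control 1), so depth differed little between groups. The 10 most abundant genes took 11.1% to 13.0% of the counts, and the mitochondrially encoded genes 0.962% to 1.45%. Counts for 27404 genes were above 0 in at least 1 library. The filterByExpr function of edgeR kept 13800 genes for testing, and these held at least 99.9% of the counts in every library. Pairs of libraries of 1 group differed by far more than sampling noise (chi-square per gene of 2.59 to 17.3 over genes with at least 20 counts in the pair), so no library was counted as a repeat of another.

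Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM (trimmed mean of M-values), a means model with 1 coefficient per group was fitted to all 12 libraries, and genes were tested with the robust quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over the 13800 genes of each comparison, with a threshold of 0.05. Every adjusted p of a gene given without another tool's name comes from this test, and ± beside a log2 fold change is its standard error, taken as the fold change over the square root of F. Levels are CPM, as the cpm function of edgeR gives them on TMM-scaled library sizes, shown as mean ± SD of 3 libraries. The 6 comparisons were Pg against control in cHet and in cKO, cKO against cHet in controls and under Pg, the mean of both genotype differences, and the interaction, which is the Pg response in cKO minus that in cHet. The interaction equals the genotype difference under Pg minus that in controls, so it shares its libraries with both genotype comparisons and is tied to them by construction.

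Gene lists were fixed before the data were examined, 34 in all. They covered immediate early genes, the NF-kB pathway, cytokines, chemokines, interferon response, feedback inhibitors, macrophage activation and identity, the inflammasome, Toll-like receptors, integrins with their signalling and alpha9beta1 ligands, osteoclasts and their repressors, matrix metalloproteinases, glycolysis, cholesterol synthesis and LXR targets. They also covered NRF2 targets, heat shock, cell cycle, MHC class II, phagocytic receptors, mitochondrially encoded genes and markers of monocytes, neutrophils, dendritic, T and NK, B and plasma, mast, erythroid and stromal cells. Each list with at least 5 tested genes was tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, which asks whether the list's genes changed more in 1 direction than the other genes. P-values were adjusted over the lists of a comparison. Because the result depends on that correlation, the test was repeated with the correlation estimated from the data, and p-values of that test are named as such. Counts "adjusted over the list alone" use the same gene p-values with the adjustment restricted to the list. Genes named in the text follow a rule fixed before the data were examined: Itga9 and Lyz2 always; up to 10 genes with the largest rise and 10 with the largest fall in each comparison, among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the libraries of the groups; and from each list up to 4 members past the threshold with the smallest p, filled up with the members of largest mean expression where fewer passed. For the mean genotype difference both differences had to have the same sign in place of the separation of libraries, and for the interaction neither was asked. Genes named Gm with digits, Rik or -ps were passed over. Slc7a11, H2-Eb1, Tmsb4x, Ddx3y, Xist, Tagln, Gm21887, BC022960, Gm15246, Gm15232, Gm15247 and Itgax fall outside this rule and were chosen after their values were seen.

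The test was checked on simulated counts for 13447 to 13493 genes per comparison, with 200 genes changed by known amounts. For the Pg comparison in cHet it recovered 71.6% of genes changed 2-fold and 89.4% of those changed 4-fold, and 4% of its calls were false. For the genotype comparison in controls these values were 73.1%, 93.9% and 6.86%. For the interaction they were 64.2%, 74.2% and 4.62%, and 29.9% of genes changed 1.5-fold were recovered. None of the 33 unchanged lists was called in any comparison (0 of 33 with camera). The simulated genes varied independently and the unchanged lists were random, so this does not check the list test where members are correlated. In the measured data the estimated correlation reached 0.71 for the interferon list in the interaction.

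Alternatives planned before the data were examined were relative log expression and upper-quartile scaling, no filter or a filter of CPM of at least 1 in at least 3 libraries, DESeq2 1.42.0 and limma-voom. Further planned ones were the replicate number as a block over all groups or within a genotype, only the 6 libraries compared, a minimum absolute log2 fold change of 1, and leaving out each library in turn. For gene lists they included fry from limma, and for windows around the engineered genes 10 Mb and 40 Mb in place of 20 Mb. Alternatives added after the data were seen were scaling by library size alone, a term for a pattern of library deviations that crossed the groups, fits within each side of that pattern, and counts without genes of the distal X chromosome. Counts without the genes that follow the mean of the stromal list were also run and are not given, since the genotype difference itself decides which genes follow it.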

Results

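Transcriptomes of bone marrow-derived macrophages were compared in a 2 by 2 design, with cHet or cKO genotype and with or without Pg for 2 hours, with 3 libraries in each of the 4 groups. The series title places the study in periodontal inflammation and the integrin alpha9beta1, an adhesion receptor whose alpha chain is encoded by Itga9. The total counts were 16793803, 15717884 and 14730553 in the cHet control libraries and 15718478, 15402070 and 16245929 in the cHet Pg libraries. They were 15648965, 14527674 and 15700691 in the cKO control libraries and 15987209, 15361576 and 15867433 in the cKO Pg libraries. In a principal component analysis of the 2000 most variable genes, the first component held 51.5% of the variance and separated Pg from control libraries, and the second held 20.9% and separated cKO from cHet libraries.

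Itga9 (ENSMUSG00000039115, chromosome 9, 118606690 to 118901003, plus strand, mm10, protein-coding) was lower in every cKO library than in every cHet library. In controls its level was 23.0 ± 8.06 CPM (SD, n = 3) in cHet and 7.98 ± 3.09 CPM (SD, n = 3) in cKO, and under Pg 28.9 ± 8.27 and 11.0 ± 2.91 CPM (SD, n = 3 each). Single cHet control libraries held 32.3, 17.9 and 18.9 CPM and cKO control libraries 11.5, 5.98 and 6.42 CPM. With Pg the cHet libraries held 19.4, 34.0 and 33.4 CPM and the cKO libraries 13.6, 11.6 and 7.84 CPM. Averaged over both treatments, the log2 difference between cKO and cHet was -1.46 ± 0.26 with an adjusted p of 0.0118. In controls alone it was -1.53 ± 0.37 (adjusted p 0.0497), a call lost without any 1 of 5 of the 6 control libraries, and under Pg alone -1.39 ± 0.36 (adjusted p 0.125), short of the threshold. Reads from Itga9 remained in all 6 cKO libraries. The labels do not say which exons were targeted, and a count over the whole gene includes transcripts that lack only the targeted part.

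Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321, minus strand), the macrophage lysozyme gene whose locus carries Cre recombinase in Lyz2-Cre mice, lay between 17628 and 22005 CPM in the 6 cHet libraries and between 8746 and 10978 CPM in the 6 cKO libraries. Its log2 difference was -0.97 ± 0.06 over both treatments with an adjusted p of 6.4e-08. The neighbouring paralog Lyz1 (chromosome 10, 117287797 to 117292868) went the other way, from 14.4 ± 5.35 to 88.5 ± 42.8 CPM (SD, n = 3 each) in controls, with a mean log2 difference of 2.78 ± 0.31 (adjusted p 0.00104). Lyz1 and Lyz2 are similar in sequence, so reads assigned to Lyz1 are uncertain. A constant share of misassigned Lyz2 reads would have fallen with Lyz2 in cKO, opposite to the rise of Lyz1. Of the tested genes within 20 Mb of Itga9, 11 of 232 (4.74%) differed between genotypes against 665 of 13567 elsewhere (4.90%, odds ratio 0.966, two-sided Fisher's exact p 1). Near Lyz2 they were 9 of 141 (6.38%) against 4.88% elsewhere, a difference short of the threshold (odds ratio 1.33, two-sided Fisher's exact p 0.428). The genotypes thus differed in Lyz2 as well as Itga9, and in a segment of chromosome X described below. The genotype comparisons and the interaction therefore compare cKO with cHet as labelled and cannot single out the loss of Itga9.

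**Figure D1:**
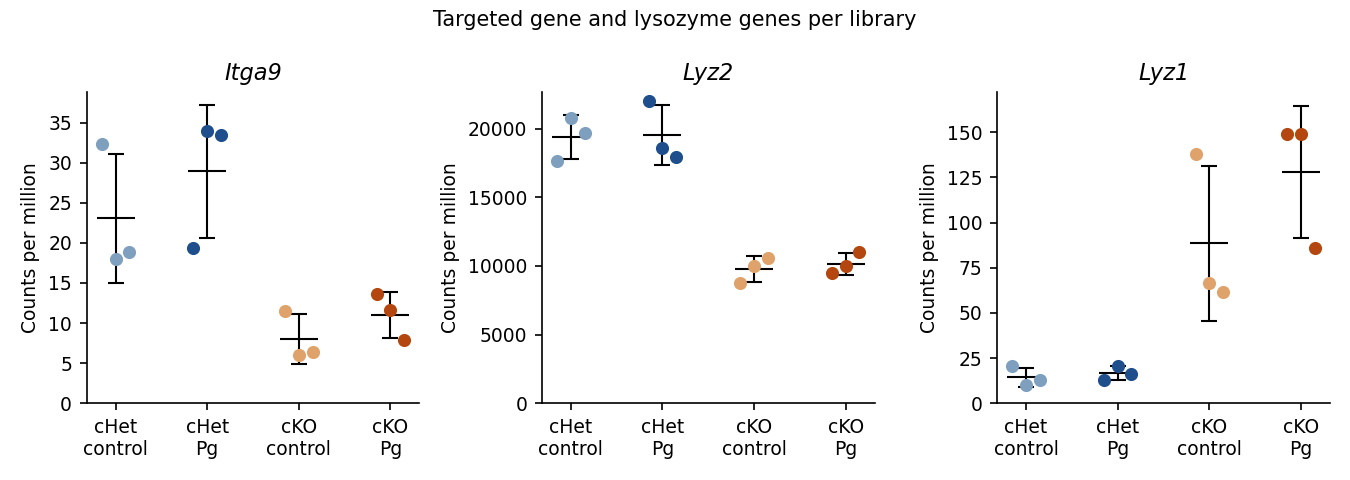
CPM of Itga9, Lyz2 and Lyz1 in each of the 12 libraries, by group, with 1 point per library and bars for the mean and SD of 3. Itga9 lies between 17.9 and 34.0 CPM in cHet and between 5.98 and 13.6 CPM in cKO, and the ranges of the genotypes do not overlap for any of the 3 genes.

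In cHet macrophages, 2 hours with Pg raised genes of inflammation, of its feedback control and of the antioxidant response. Il10, which encodes an anti-inflammatory cytokine, rose from 5.31 ± 1.38 to 175 ± 1.55 CPM (SD, n = 3 each), a log2 change of 5.04 ± 0.13 (adjusted p 1.7e-13). Ptgs2, the inducible cyclooxygenase, rose by 4.82 ± 0.14 (adjusted p 3.5e-12), and the neutrophil-attracting chemokines Cxcl3 and Cxcl1 rose by 4.48 ± 0.11 and 4.25 ± 0.15 on the log2 scale. Sphk1, Fosb, Serpinb2, Il1a, Il1rn and Nr4a3 completed the 10 named genes with the largest rises, between 3.69 and 4.98. Among falls, the interferon-induced Ifit3b changed by -2.52 ± 0.44, the pro-apoptotic Bmf by -2.45 ± 0.23, Usp2 by -2.42 ± 0.18 and the transcription factor Hhex by -2.13 ± 0.13. In all, 4980 of 13800 genes changed, 2490 up and 2490 down, and 1109 of them by at least 2-fold (685 up, 424 down).

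The inflammatory lists rose together in cHet. Of 17 inflammatory cytokines, 12 rose and 5 did not pass (14 rose when adjusted over the list alone), including Il1b at 3.02 ± 0.09 and Tnfsf9 at 2.86 ± 0.09. The list had a camera adjusted p of 5.3e-18 (adjusted p = 0.013 with an estimated correlation). Of 19 chemokines, 12 rose, 2 fell and 5 did not pass (13 up and 3 down adjusted over the list alone; adjusted p = 0.0382 with an estimated correlation). Cxcl2 was at 3.25 ± 0.14 and Ccl2 at 2.14 ± 0.16. Of 19 NF-kB pathway genes, 16 rose and none fell by the edgeR test (16 adjusted over the list alone; adjusted p = 0.00827 with an estimated correlation). The inhibitors Tnfaip3 and Nfkbia stood at 2.13 ± 0.07 and 1.51 ± 0.06. Anti-inflammatory feedback genes gave 16 rises and 1 fall among 18 (the same counts adjusted over the list alone; adjusted p = 0.000438 with an estimated correlation). The phosphatase gene Dusp1 rose by 2.57 ± 0.08 and Zfp36, whose product destabilises cytokine mRNAs, by 1.79 ± 0.07, while Il10ra changed by -0.69 ± 0.06. Immediate early genes gave 14 rises and 3 falls among 19 (the same adjusted over the list alone; adjusted p = 0.0382 with an estimated correlation). Among them were Myc at 1.95 ± 0.08 and Fosl1 at 3.23 ± 0.17. Of 16 inflammatory macrophage activation markers, 13 rose and 3 did not pass (13 adjusted over the list alone; adjusted p = 0.0248 with an estimated correlation). Cd86 was at 1.36 ± 0.10 and Cd80 at 1.12 ± 0.10.

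Antioxidant genes and integrin ligands also rose in cHet. NRF2 and oxidative stress genes gave 13 rises among 15 (13 adjusted over the list alone; adjusted p = 0.000438 with an estimated correlation). Slc7a11, the cystine importer that feeds glutathione synthesis, rose by 3.53 ± 0.16, Srxn1 by 2.86 ± 0.08, and the haem-degrading Hmox1 from 1139 ± 240 to 6175 ± 110 CPM (SD, n = 3 each). Integrin alpha9beta1 ligands gave 6 rises among 14 (7 up and 1 down adjusted over the list alone; adjusted p = 0.0382 with an estimated correlation). Members were Thbs1 at 1.78 ± 0.18 and Vcam1 at 1.11 ± 0.12. Type I interferon and interferon response genes went down on balance, with 3 rises and 11 falls among 27 (the same adjusted over the list alone) and a camera adjusted p of 0.0269, a call lost with an estimated correlation (adjusted p = 0.743 with an estimated correlation). It was also lost without cHet control 1 (adjusted p 0.130) and without cHet Pg 1 (adjusted p 0.166). The antiviral genes Mx2 and Ifit1 changed by -1.22 ± 0.23 and -1.29 ± 0.26.

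A further 6 lists passed the preset test in cHet and lost the call with an estimated correlation. These were matrix metalloproteinases (7 up, 1 down of 17; adjusted p = 0.114 with an estimated correlation), with the collagenase Mmp13 at 2.67 ± 0.13 and the urokinase receptor Plaur at 2.10 ± 0.13. Next were glycolysis and hypoxia genes (10 up, 2 down of 20; adjusted p = 0.192 with an estimated correlation), with the glucose transporter Slc2a1 at 1.38 ± 0.08. Integrin signalling genes gave 14 up and 0 down of 27 by the edgeR test (adjusted p = 0.229 with an estimated correlation) and heat shock genes 8 up of 15 (adjusted p = 0.191 with an estimated correlation). Osteoclast genes gave 6 up and 2 down of 13 (adjusted p = 0.32 with an estimated correlation), with Jdp2 at 2.08 ± 0.08 up and Ppargc1b at -2.44 ± 0.26 down. Alternative activation markers gave 5 up of 13 (adjusted p = 0.114 with an estimated correlation). The remaining lists did not pass, among them cell cycle genes (2 up of 25), MHC class II genes (2 up, 1 down of 11) and macrophage identity genes (5 up, 1 down of 20).

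Fold changes by Pg are relative to the TMM scaling. Scaling by library size alone, added after the data were seen, lowered the median log2 change of all genes by 0.24 in both genotypes and turned the 50% of calls that were rises into 19.1% in cHet, and 49.7% into 18.7% in cKO. A shift of this size puts the medians of 4 called lists below 0: alternative activation markers in cHet (0.24), and alpha9beta1 ligands (0.23), glycolysis and hypoxia genes (0.23) and heat shock genes (0.21) in cKO.

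In cKO macrophages Pg changed 4687 genes, 2328 up and 2359 down, 1150 of them by at least 2-fold (672 up, 478 down). Il10 rose by 5.80 ± 0.13 on the log2 scale to 189 ± 8.81 CPM (SD, n = 3), Ptgs2 by 5.39 ± 0.14 and Cxcl1 by 5.03 ± 0.16 (adjusted p 2.1e-10). Fosb, Sphk1, Il1a, Il6, Hbegf, Fosl1 and Cxcl3 rose by 4.19 to 5.88. Among falls, the interferon-induced Mx1 changed by -2.83 ± 0.36 (adjusted p 0.00038), the transcription factor Hhex by -2.75 ± 0.14, Cmpk2 by -2.75 ± 0.33, Ifit1 by -2.63 ± 0.27 and Mx2 by -2.59 ± 0.25. Tgtp2, Enc1, Ifit3b, the GTPase gene Irgm2 and Arrdc3 completed the 10 named genes with the largest falls, between -2.52 and -2.27.

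Cytokines (13 of 17 up), NF-kB pathway genes (16 of 19 up), immediate early genes (16 up and 1 down of 19), feedback genes (15 up and 1 down of 18) and NRF2 genes (13 of 15 up) kept their calls with an estimated correlation, at adjusted p = 0.00474 with an estimated correlation for the first 3 and 0.000159 and 0.000307 for the last. Adjusted over the list alone, the rises numbered 13, 16, 17, 16 and 13. Examples were Il1b at 3.63 ± 0.09, Tnfaip3 at 2.65 ± 0.07, Junb at 1.36 ± 0.06, Dusp1 at 3.69 ± 0.09 and Txnrd1 at 2.40 ± 0.07. Interferon response genes gave 1 rise and 19 falls among 27 (the same adjusted over the list alone), and had a camera adjusted p of 2.6e-08 that was lost with an estimated correlation (adjusted p = 0.392 with an estimated correlation). Irf1 was the member that rose, by 0.93 ± 0.09. Chemokines gave 10 up and 3 down of 19 (adjusted p = 0.0503 with an estimated correlation) and inflammatory macrophage activation markers 9 up and 1 down of 16 (adjusted p = 0.0784 with an estimated correlation). The other 6 lists past the preset threshold were alternative activation (6 up of 13; adjusted p = 0.0546 with an estimated correlation), alpha9beta1 ligands (6 up, 1 down of 14; 0.0784), osteoclast genes (6 up, 2 down of 13; 0.359), matrix metalloproteinases (7 up, 1 down of 17; 0.151), glycolysis genes (8 up, 1 down of 20; 0.292) and heat shock genes (8 up of 15; 0.248), each p being the adjusted p with an estimated correlation.

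Both genotypes answered Pg with largely shared calls. Of the rises, 1722 were called in both (420 expected from independent lists), of the falls 1626 (426 expected), and 14 genes were called in opposite directions. Across the 13800 genes, which are not independent replicates, the log2 changes correlated with r = 0.786 and a slope of 0.843 for cKO on cHet. These comparisons share no library.

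**Figure D2:**
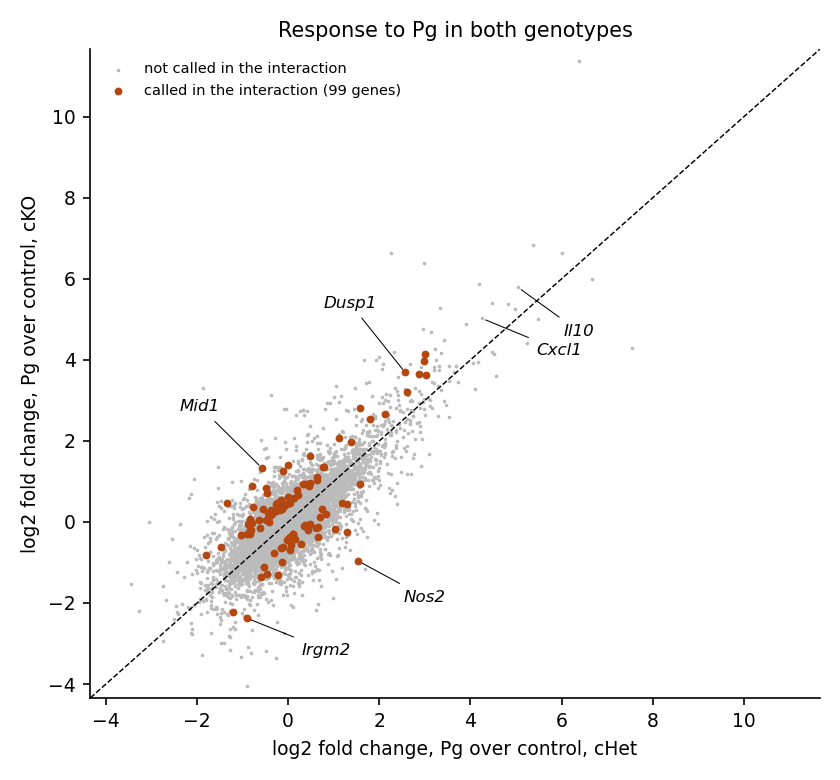
Log2 fold change by Pg in cKO (vertical axis) against cHet (horizontal axis) for each of the 13800 tested genes, with the 99 genes called in the interaction in colour and the line of equal change dashed. Most genes lie near the line (r = 0.786 across genes), Il10 and Cxcl1 rise in both, and Nos2 lies at 1.54 in cHet and -0.97 in cKO.

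The comparison of cKO with cHet in controls asks which genes differ with the genotype before Pg. Among genes lower in cKO, the extracellular matrix gene Sparc changed from 7.22 ± 0.906 to 0.484 ± 0.268 CPM (SD, n = 3 each), a log2 difference of -3.89 ± 0.28 (adjusted p 2.2e-07). The basement membrane genes Hspg2 and Col4a1 changed by -3.56 ± 0.30 and -3.46 ± 0.26, and Fcna, a lectin gene, by -1.78 ± 0.17. Cxcl1 was lower, at -1.83 ± 0.16 (adjusted p 2.5e-05). Higher in cKO were Mid1 at 3.16 ± 0.23, Lrmda at 3.12 ± 0.23, the immunoglobulin gene Ighg2b at 2.60 ± 0.44 and Gdf3 at 2.15 ± 0.25. In all, 711 genes differed, 294 higher and 417 lower in cKO, 188 of them by at least 2-fold (47 higher, 141 lower). The count fell to 426 without cHet control 2, 355 without cHet control 3 and 319 without cKO control 3.

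Immediate early and feedback genes were lower in unstimulated cKO cells. Of 19 immediate early genes, 7 were lower and none higher by the edgeR test (15 lower adjusted over the list alone; adjusted p = 0.0378 with an estimated correlation). Junb stood at -0.63 ± 0.06, Ier3 at -0.98 ± 0.11 and Ier2 at -0.77 ± 0.12. Of 18 feedback genes, 8 were lower and 1 higher (9 and 2 adjusted over the list alone; adjusted p = 0.0457 with an estimated correlation). Dusp1 stood at 226 ± 16.3 CPM in cHet and 92.9 ± 10.1 CPM in cKO (SD, n = 3 each), Zfp36 at -0.77 ± 0.07 and Irak3 at 0.50 ± 0.07. Cytokines gave 4 lower of 17 (6 adjusted over the list alone; adjusted p = 0.195 with an estimated correlation), with Il1b at -0.57 ± 0.08 and Tnfsf9 at -0.94 ± 0.09. Chemokines gave 4 lower of 19 (4 adjusted over the list alone; adjusted p = 0.585 with an estimated correlation). The chemokine call was lost without cHet control 1 (adjusted p 0.145), cKO control 2 (0.0908) or cKO control 3 (0.0715). MHC class II genes gave 2 higher of 11 (5 adjusted over the list alone; adjusted p = 0.499 with an estimated correlation), with H2-Ab1 at 0.62 ± 0.14. The other lists called at the preset correlation lost the call with an estimated one: Toll-like receptor genes (4 higher of 26; adjusted p = 0.287 with an estimated correlation), osteoclast repressors (1 lower of 9; 0.162), matrix metalloproteinases (2 lower of 17; 0.499), mast cell markers (1 lower of 8; 0.585) and mitochondrially encoded genes (2 higher of 13; 0.585).

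Stromal and fibroblast markers formed the list with the largest shift. In controls 9 of 10 tested members were lower in cKO and none was higher by the edgeR test (10 lower adjusted over the list alone), with a median log2 difference of -3.89 and an adjusted p = 3.9e-05 with an estimated correlation. Under Pg 8 of 10 were lower (10 adjusted over the list alone; median -3.04; adjusted p = 7.8e-05 with an estimated correlation). The collagen gene Col1a2 stood at 6.02 ± 0.36 CPM in cHet and 0.298 ± 0.096 CPM in cKO controls (SD, n = 3 each), and the proteoglycan gene Bgn at 6.77 ± 1.09 and 0.315 ± 0.221 CPM. Of 14 integrin alpha9beta1 ligands, with medians of -0.17 in controls and -0.21 under Pg, 2 were lower in controls, Tnc at -3.27 ± 0.40 and Vcam1 at -0.86 ± 0.12 (3 adjusted over the list alone; adjusted p = 0.0603 with an estimated correlation), and 2 under Pg (4 adjusted over the list alone; adjusted p = 0.0135 with an estimated correlation). Tnc, an extracellular matrix gene, was at 4.32 ± 0.576 CPM in cHet and 0.436 ± 0.404 CPM in cKO controls, a fall like that of the stromal markers. The ligand list had means of -0.36 in controls and -0.64 under Pg, further from 0 than its medians, and was not tested without Tnc.

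Under Pg, 255 genes differed between genotypes, 90 higher and 165 lower in cKO, 122 by at least 2-fold (26 higher, 96 lower). Nos2, the inducible nitric oxide synthase, was at 9.53 ± 4.08 CPM in cHet and 1.54 ± 0.47 CPM in cKO (SD, n = 3 each), a log2 difference of -2.62 ± 0.31 (adjusted p 9.2e-05). The complement genes Cd59a and C4b were lower, at -1.78 ± 0.23 and -1.68 ± 0.23. So were Cxcl1, at -1.05 ± 0.13 (adjusted p 0.00071), and Hspg2, Sparc and Col4a1, at -3.58 ± 0.31, -3.16 ± 0.26 and -2.81 ± 0.24. Mid1 at 5.07 ± 0.24, Lrmda at 3.07 ± 0.24, Tlr7 at 1.14 ± 0.08 and Tlr8 at 1.09 ± 0.08 were higher. Removal of cHet Pg 2 left 168 genes and of cKO Pg 2 left 153.

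Interferon response genes gave 2 lower of 27 under Pg, Gbp5 at -0.54 ± 0.09 and Mx2 at -1.36 ± 0.26, and 9 lower adjusted over the list alone. The camera adjusted p of 7.5e-10 was lost with an estimated correlation (adjusted p = 0.619 with an estimated correlation). The Mx2 call was lost without any 1 of the 6 Pg libraries, with adjusted p of 0.0768 to 0.136. Chemokines gave 2 lower of 19, Cxcl1 and Cxcl3 (2 adjusted over the list alone; adjusted p = 0.619 with an estimated correlation), a call lost without cHet Pg 2 (0.0696), cHet Pg 3 (0.234) or cKO Pg 3 (0.0872). MHC class II genes had no member past the threshold by the edgeR test and 6 of 11 higher adjusted over the list alone (adjusted p = 0.619 with an estimated correlation). Matrix metalloproteinases and inhibitors gave 1 lower of 17, Timp3 at -0.85 ± 0.20 (6 adjusted over the list alone; adjusted p = 0.577 with an estimated correlation). Toll-like receptor genes (3 higher of 26; adjusted p = 0.38 with an estimated correlation), neutrophil markers (1 lower of 16; 0.619) and mast cell markers (0 past the threshold by the edgeR test and 2 lower of 8 adjusted over the list alone; 0.619) were likewise called at the preset correlation alone.

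Averaged over treatment, 677 genes differed between genotypes, 294 higher and 383 lower in cKO, 198 by at least 2-fold (47 higher, 151 lower). The genotype differences measured in controls and under Pg, which share no library, had 48 higher and 97 lower calls in common (1.92 and 4.99 expected from independent lists), 6 opposite calls and r = 0.576 across genes. MHC class II genes, which present antigen to T cells, gave 5 higher of 11, H2-Ab1 at 0.62 ± 0.10, Cd74 at 0.76 ± 0.13, H2-Aa at 0.65 ± 0.13, Ciita and H2-Eb1 (6 adjusted over the list alone; adjusted p = 0.313 with an estimated correlation). H2-Eb1 ends a run of 5 neighbouring genes on chromosome 17 with a median log2 difference of 0.52, the highest outside the distal X chromosome. Calls of neighbouring members may therefore not be independent. Toll-like receptor pathway genes gave 4 higher of 26 (6 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation), Tlr7 at 1.08 ± 0.06, Tlr8 at 1.00 ± 0.06, Tlr9 at 0.28 ± 0.07 and Tlr2 at 0.19 ± 0.05. Alternative activation markers gave 2 lower of 13, Arg1 at -1.31 ± 0.24 and Clec10a at -0.29 ± 0.04, and did not pass as a list. Other lists called at the preset correlation, with their adjusted p with an estimated correlation, were immediate early genes (4 lower; 0.252), cytokines (4 lower; 0.313), chemokines (1 lower; 0.499), interferon genes (2 lower; 0.722), feedback genes (5 lower, 1 higher; 0.192), matrix metalloproteinases (5 lower; 0.313), neutrophil markers (1 lower; 0.499) and mast cell markers (1 lower; 0.414). Stromal markers (10 of 10 lower, adjusted p = 2.0e-05) and alpha9beta1 ligands (3 of 14 lower, adjusted p = 0.012) kept their calls with an estimated correlation. The ligand list had a median of -0.18 and a mean of -0.50, with Tnc at -4.66 beside a stromal median of -3.47. The ligand list was not tested without Tnc, so its call cannot be told apart from the fall of the stromal markers.

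**Figure D3:**
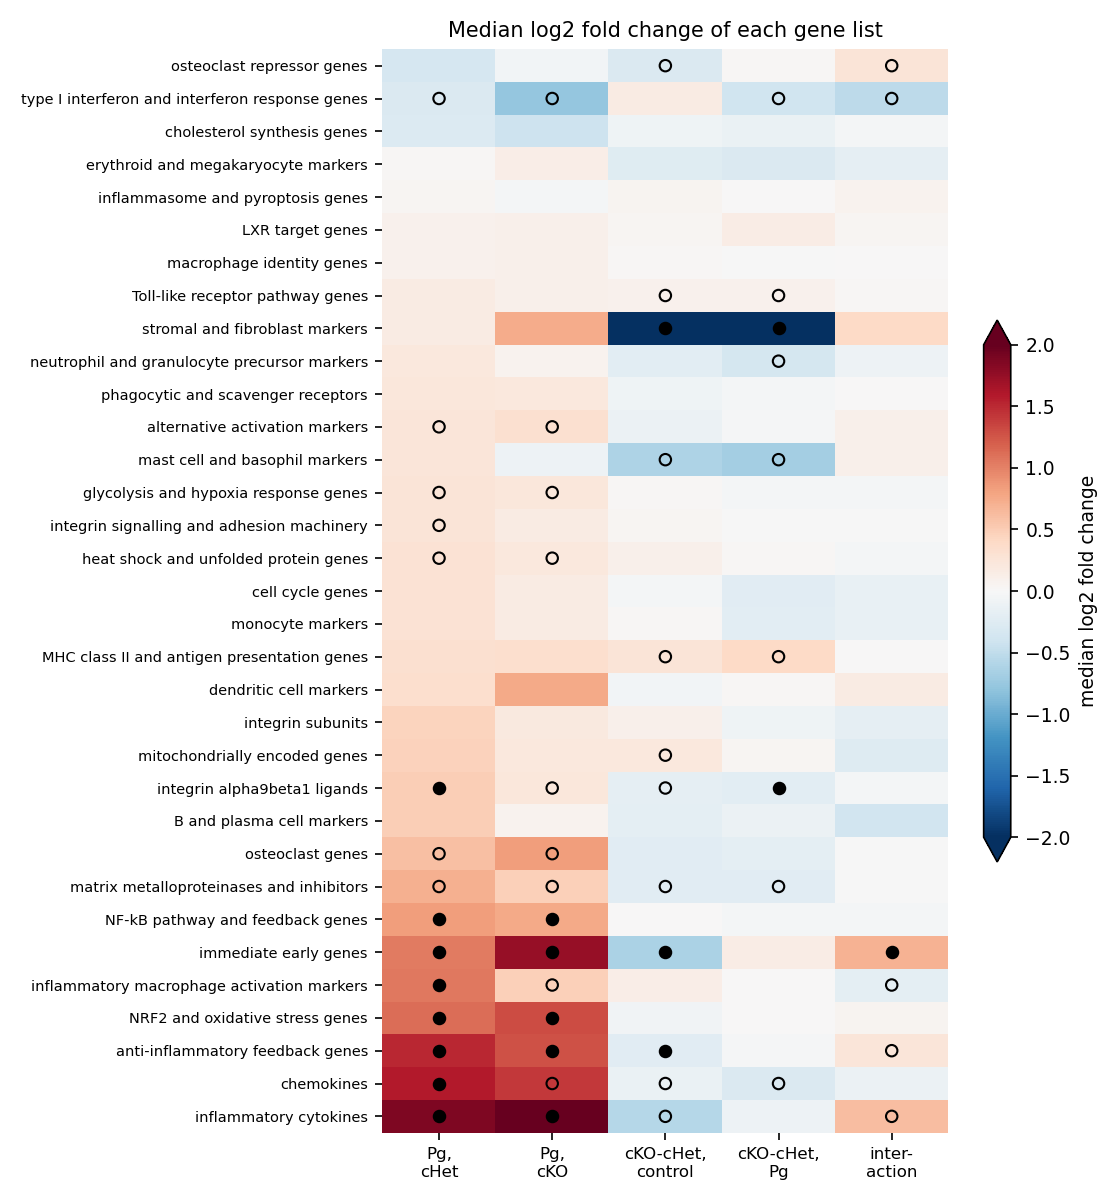
Median log2 fold change of each gene list (vertical axis) in each comparison (horizontal axis), in colour, limited at 2 in either direction. An open circle marks a camera adjusted p below 0.05 and a filled circle one that also held with an estimated correlation, as for the stromal list in both genotype comparisons.

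Tlr7 and Tlr8 lie beside each other at the end of chromosome X, and their neighbours differed in the same way. All 9 tested protein-coding genes from 167207093 to 170019281 on chromosome X were higher in cKO. Their median log2 difference was 1.00 over both treatments, 1.02 in controls and 1.06 under Pg. Every cKO library lay above every cHet library for 9 of these 9 genes. Tmsb4x, which encodes an actin-binding peptide, stood at 2026 ± 48.4 CPM in cHet and 4282 ± 192 CPM in cKO controls (SD, n = 3 each), and Hccs, a mitochondrial haem lyase gene, at 18.9 ± 0.529 and 40.5 ± 5.06 CPM. Mid1, the last but 1 of these genes, differed by 4.11 ± 0.17, and it reaches the pseudoautosomal boundary, where reads can be shared with the Y chromosome. The 10 nearest protein-coding genes before them with a mean log2 CPM of at least 1, from 162901238 to 166518567, had a median of 0.13 over both treatments and none was called higher by edgeR. This segment was examined after its values were seen. Without Tlr7 and Tlr8 the Toll-like receptor list had adjusted p of 0.113 in controls and 0.111 under Pg, and kept its call over both treatments at 0.0436 (adjusted p = 0.499 with an estimated correlation).

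**Figure D4:**
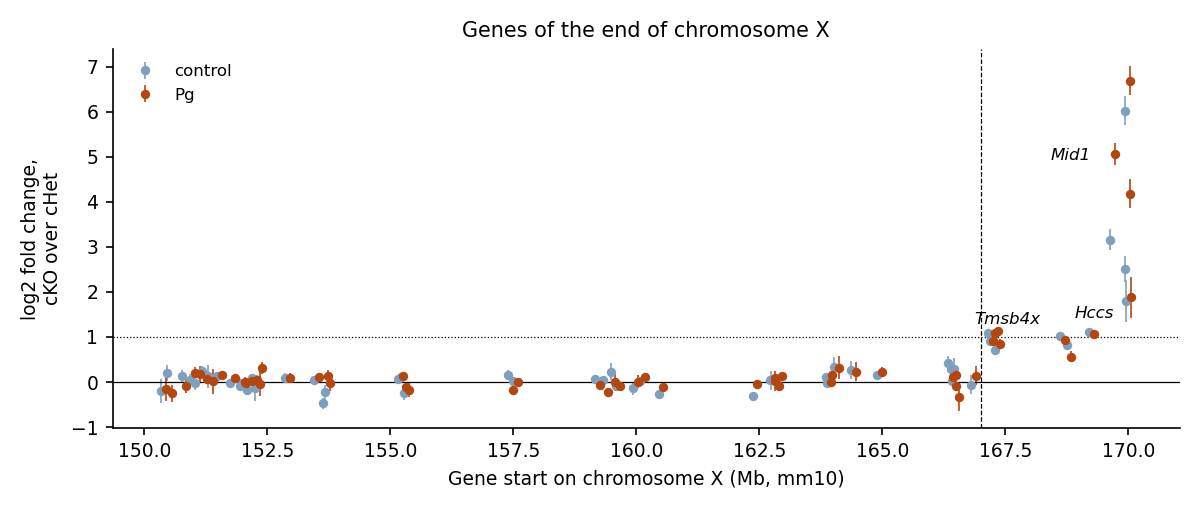
Log2 difference of cKO over cHet (vertical axis, bars show the standard error) of the tested genes with a mean log2 CPM of at least 1 near the end of chromosome X against gene start in Mb of mm10 (horizontal axis), in controls and under Pg. The dashed line lies between 166518567 and 167207093. The genes left of it lie between -0.47 and 0.43, and the genes right of it between 0.56 and 6.68, with Mid1 at 3.16 in controls and 5.07 under Pg.

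The interaction tests whether the Pg response differs between genotypes. Dusp1 rose by 1.12 ± 0.11 more in cKO (adjusted p 0.00028), from 92.9 ± 10.1 to 1199 ± 94.0 CPM against 226 ± 16.3 to 1342 ± 36.5 CPM in cHet (SD, n = 3 each). Junb, Zfp36, Dusp5, Ier3 and Tnfsf9 likewise rose more in cKO, by 0.60 ± 0.08, 0.76 ± 0.10, 0.99 ± 0.14, 0.96 ± 0.15 and 0.79 ± 0.12 on the log2 scale. For each of these 6 genes the genotypes differed in controls and not past the threshold under Pg. Nos2 rose in cHet (1.54 ± 0.27) and fell in cKO (-0.97 ± 0.34), an interaction of -2.50 ± 0.43 (adjusted p 0.0116), lost without cKO Pg 2 (adjusted p 0.0523) and with limma-voom (0.0928), in a range of 1.3e-10 to 0.0928 over the alternatives. Irgm2 fell more in cKO, with an interaction of -1.47 ± 0.20 (adjusted p 0.0063), and AW112010 had one of -1.09 ± 0.18. In all, 99 genes were called, 63 with a higher and 36 with a lower log2 change in cKO, 19 of them by at least 2-fold. The number was 61, 42, 53, 42, 45 and 43 without cHet control 2 or 3, cHet Pg 2, cKO control 3 or cKO Pg 1 or 2, and 207 without cKO Pg 3.

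Immediate early genes had a higher log2 change by Pg in cKO, with 2 of 19 called, Junb and Ier3, 14 adjusted over the list alone, a median of 0.70 and an adjusted p = 0.0425 with an estimated correlation. The median genotype difference of this list was -0.63 in controls and 0.15 under Pg, where the list did not pass (camera adjusted p 0.189). The higher change thus went mainly with a lower level in unstimulated cKO cells. Osteoclast repressors were called as a list with none of 9 members past the threshold by the edgeR test (1 up adjusted over the list alone; adjusted p = 0.245 with an estimated correlation). Feedback genes gave 4 of 18 called (7 up and 1 down adjusted over the list alone; adjusted p = 0.137 with an estimated correlation), Dusp1, Zfp36, Dusp5 and Zc3h12c. Interferon response genes had a median of -0.52, with Irf1 called at 0.60 ± 0.12 in the opposite direction (1 up and 7 down adjusted over the list alone; adjusted p = 0.481 with an estimated correlation). Inflammatory macrophage activation markers gave 3 of 16 with a lower response, Nos2, Acod1 at -0.57 ± 0.10 and Cd38 at -0.84 ± 0.17 (3 down and 1 up adjusted over the list alone; adjusted p = 0.471 with an estimated correlation). Cytokines gave 2 of 17 with a higher response, Tnfsf9 and Il1b at 0.61 ± 0.12 (5 up and 1 down adjusted over the list alone; adjusted p = 0.471 with an estimated correlation). Over the 3162 genes that Pg raised on average, a list chosen on these samples, the median interaction was -0.02 (camera p 0.563). Over the 3356 genes it lowered, it was 0.006 (camera p 0.894). The interaction of Itga9 itself was 0.14 ± 0.52 (adjusted p 0.956).

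**Figure D5:**
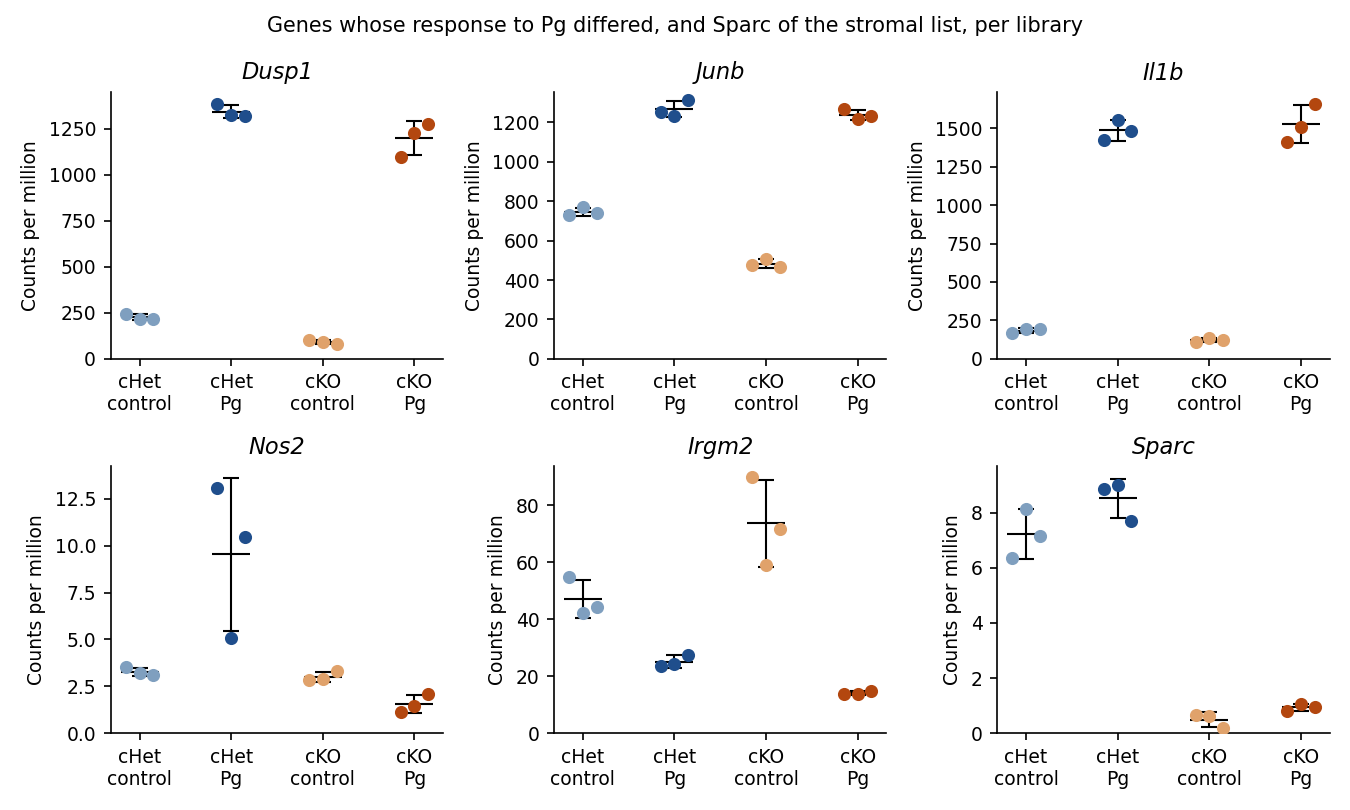
CPM of Dusp1, Junb, Il1b, Nos2, Irgm2 and the stromal marker Sparc in each of the 12 libraries by group, with 1 point per library and bars for the mean and SD of 3. Dusp1 in controls stands at 226 CPM in cHet and 92.9 CPM in cKO and at 1342 and 1199 CPM under Pg, while Nos2 reaches 9.53 CPM in cHet and 1.54 CPM in cKO under Pg.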

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

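The tests of the distal X chromosome, of the share of macrophages and of the replicate number were chosen after the results were seen, whereas the tests of the untested stromal markers, of independent variation and of the splits were not. The Pg response differed between genotypes, by the interaction test, for 99 genes and, at the preset correlation, 6 lists, of which only immediate early genes kept the call with an estimated correlation (adjusted p = 0.0425). Their median genotype difference was -0.63 in controls and 0.15 under Pg. The log2 change by Pg was higher in cKO for Mid1 by 1.91, Dusp8 by 1.41, Csrnp1 by 1.24, Alms1 by 1.19, Ppp1r15a by 1.16, Eid3 by 1.15, Dusp1 by 1.12, Dusp5 by 0.99, Ier3 by 0.96 and, with a smaller fall in cKO, Fam214a by 0.98. It was also higher for Tnfsf9 by 0.79, Zfp36 by 0.76, Il1b by 0.61, Junb by 0.60, Irf1 by 0.60, Tnfaip3 by 0.52, Clec10a by 0.50 and Zc3h12c by 0.40 on the log2 scale. It was lower in cKO with a log2 difference of -2.50 for Nos2, -1.47 for Irgm2, -1.21 for Lars2, -1.09 for AW112010, -1.03 for Col18a1 and -1.01 for Tent5a. The difference was -0.85 for Parp14, -0.85 for Myo10, -0.84 for Cd38, -0.82 for Dtx3l, -0.63 for Src and -0.57 for Acod1. The list medians were 0.70 for immediate early genes, 0.61 for cytokines, -0.52 for interferon genes, 0.24 for feedback genes, -0.20 for activation markers and 0.26 for osteoclast repressors, the last 5 with adjusted p = 0.471, 0.481, 0.137, 0.471 and 0.245 with an estimated correlation. Of 20 alternatives, Csrnp1 and Dusp8 lost the call in 10, Mid1, Ppp1r15a and Src in 9, Irf1 and Zc3h12c in 8, Cd38 in 7, Lars2 in 6, Il1b in 5, Alms1 in 3, Nos2 in 2 and Clec10a and Tnfaip3 in 1. Dusp1, Dusp5, Junb, Ier3, Zfp36, Tnfsf9, Irgm2, Acod1 and AW112010 kept it in all 20.

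Other splits of the libraries measure how often such counts arise without the real groups. For the interaction, 4 of 100 splits drawn from 200, the real one included, gave at least 99 genes. A first draw of 60 splits held 3 such splits, a share not under 0.05, and the draw was enlarged to 100 after that. The verdict depends on the draw and the remaining splits were not run, so chance cannot be excluded for the number of interaction genes. The highest other split gave 677 genes, because exchanging the genotypes under Pg alone turns the interaction into the sum of the genotype differences. The next gave 312 and 189, more than the real count. They kept the control groups and exchanged 2 and 1 libraries of each genotype under Pg, so part of the genotype difference enters them. Another split that exchanged 1 library of each genotype under Pg gave 12, so such an exchange alone need not give a high count. In the split with 312, cHet Pg 1 and cKO Pg 3, from the same side of the pattern of library deviations, stood together. Which of these gave the high counts was not tested. For lists, 64 of 100 splits gave at least 6, with a highest of 20, so chance cannot be excluded. For the mean genotype difference 1 of 100 splits, the real one, gave 677 genes and the highest other gave 312. Chance in the grouping of these libraries can thus be excluded for that number of genes. The splits treat libraries as independent, which the labels do not state, so a chance difference between mice or cultures is not excluded. For lists, 22 of 100 splits gave at least 12, with a highest of 20, so chance cannot be excluded. Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. The real and highest other counts were 4980 and 0 genes for Pg in cHet, 4687 and 0 for Pg in cKO, 711 and 0 for genotype in controls and 255 and 16 under Pg. For lists they were 15 and 22, 14 and 20, 12 and 14, and 9 and 16, with 4, 5, 2 and 3 of 10 splits as large.

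Genes at the distal end of chromosome X were higher in cKO, and of 10900 runs of 5 neighbouring genes in the genome, the 7 with all 5 genes at 0.5 or above lay here. A difference in sex between the genotypes is excluded, since the Y-linked Ddx3y had at least 970 counts and Xist at most 2 in all 12 libraries. A factor per library moves all genes alike, so the scaling between libraries is excluded by the log2 difference of 0.873 between the median of the 9 distal genes and that of the 10 before them, with the lowest of the 9 at 0.69 and the highest of those 10 at 0.33. An additional copy of this segment in the cKO mice predicts a log2 difference near 1 and may account for the median of 1.00 over 9 genes, while Mid1 at 4.11, Gm21887 at 1.84 and 4 non-coding genes of the segment at 3.34 to 6.99 lie above it. BC022960 at 1.05 and Gm15246 at 0.69 (adjusted p 0.415), also not protein-coding, lie nearer to 1. Both of these, and Gm15232 and Gm15247 among the 4, had a mean log2 CPM below 1. A response of these genes to the loss of Itga9 stays open and was not tested.

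The stromal list was lower in cKO. A lower share of macrophages in the cHet cultures would raise markers of all other cell types in cHet alike if those types kept their proportions. That is excluded as the whole cause, since list medians of 5 other cell types ran from -0.76 (mast cells) to 0.0264 (dendritic cells) beside -3.47. The neutrophil, erythroid and B cell medians were also below 0, at -0.24, -0.28 and -0.15. In the B and plasma cell list 1 member was called higher in cKO, Jchain at 1.58, and 1 lower. A smaller change in the share of macrophages, or an uneven one between the other cell types, is not excluded. Stromal cells in the cHet cultures are a candidate source: the 6 list members with too few counts to be tested held 174 counts in cHet and 49 in cKO, a CPM ratio of 3.51 (95% interval 2.54 to 4.92, counting error only), with Tagln at 23 and 31 going the other way. The most abundant markers reached mean levels in cHet of only 7.87 CPM (Sparc), 6.64 CPM (Bgn) and 6.62 CPM (Col1a2). A lower expression of these genes by cKO macrophages stays open and was not tested.

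Libraries of different groups deviated from their group means along the same genes. The first component of these deviations held 39.6% of their variance, and 20 simulations of independent libraries gave at most 13.95%. The simulations also drew each gene independently of the others. They cannot tell libraries that deviate together from independent libraries whose genes vary together, so independent variation between libraries is not excluded. A batch marked by the replicate number that moved all 4 groups alike is excluded as the source of this component. Libraries of the same number had correlations down to -0.29. Between the genotypes, same-number control libraries had correlations of 0.319, 0.0512 and 0.0603, and same-number Pg libraries -0.245, 0.0514 and -0.141. A batch by number within a treatment, or one weaker than this component, is therefore not excluded. Itga9 itself followed the component (r = 0.99 with its deviations), so the spread of Itga9 within groups belongs to this pattern. No biological explanation was tested, and the labels give no factor that separates these libraries.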

How the results depend on the processing

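The library set term, the fits within sets and scaling by library size alone were chosen after the data were seen. No named gene or list past the threshold changed direction under the alternatives run for it (0 reversed), whereas values short of the threshold did. Scaling by library size alone was run for the gene counts and not for single lists or genes, and its shift of -0.24 in the Pg comparisons would turn the medians of alternative activation markers in cHet and of alpha9beta1 ligands, glycolysis and heat shock genes in cKO. At the depth of these libraries the self-test recovered 29.9% of interactions of 1.5-fold, so small differences can be missed. No pairing by replicate number was seen across the groups: only 5 of 18 pairs of the same number correlated above 0.1. A pairing weaker than the shared deviations of the libraries is not excluded.

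A minimum log2 fold change of 1 left 1109 and 1150 genes for Pg in cHet and cKO, 188, 122 and 198 for genotype in controls, under Pg and on average, and 19 for the interaction, as fewer genes can pass. With no filter on low counts the last 4 were 1101, 507, 1102 and 389. With the library set term they were 1722, 846, 1526 and 785; this term is taken from the residuals, so it lowers the residual spread by construction. DESeq2 called 259 interaction genes and a replicate block within genotype 57, and within library set A 436 genes differed on average between genotypes, with fewer samples. Itga9 in controls missed the threshold with no filter (-1.53, adjusted p 0.0876), limma-voom (-1.54, 0.0651) and a replicate block (-1.53, 0.0767), and under Pg passed it with DESeq2 (-1.39, 0.0125) and the library set term (-1.39, 1.3e-11). Over genes called in either genotype the Pg responses had r = 0.864 and a slope of 0.928. With an estimated correlation 8, 5, 3, 2, 2 and 1 lists passed, in the order above. With fry, 24 passed for Pg in cKO, 3 for genotype under Pg and 2 for the interaction, and with the library set term 16 for genotype under Pg. Odds ratios near Itga9 were 1.298 (10 Mb), 1.12 (40 Mb) and, for calls at 0.01, 0.334. Near Lyz2 they were 2.10 (10 Mb, p 0.0887), 0.941 (40 Mb) and, for calls at 0.01, 1.75 (p 0.170). Where no reason is given, the cause was not tested.

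Without 1 library at a time, counts ran from 4102 to 5103 and 3838 to 4807 for Pg in cHet and cKO, 319 to 828, 153 to 307 and 499 to 715 for genotype in controls, under Pg and on average, and 42 to 207 for the interaction. Itga9 ran from -1.90 to -1.196 in controls, the correlation from 0.725 to 0.756, the slope from 0.741 to 0.852, and the median interaction of Pg-induced genes from -0.0568 to 0.00244 and of Pg-repressed genes from -0.0116 to 0.0202. Of named genes under all alternatives, 13028 values kept their side of the threshold, 587 lost a call, 179 gained one and 458 short of the threshold changed direction, and of lists 3029, 103, 94 and 140.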

Other observations

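The genes and libraries of the shared deviations were examined after the data were seen. Among lists that did not pass in either Pg comparison, cholesterol synthesis genes gave 4 falls of 19 in each genotype, with Fdps, an enzyme of the mevalonate pathway, at -1.15 in cHet. Toll-like receptor genes gave 10 up and 5 down of 26 in cHet and 11 up and 5 down in cKO, inflammasome genes 5 up and 4 down of 15 and 3 up and 4 down, and integrin subunits 7 up and 4 down of 19 and 4 up and 3 down, with Itga5, a fibronectin receptor chain, at 1.00 ± 0.06 in cHet. LXR targets gave 2 and 3 rises of 12, phagocytic and scavenger receptors 5 and 5 of 17, dendritic cell markers 3 of 12 in cHet and 5 up and 1 down in cKO, and mitochondrially encoded genes 4 and 0 of 13. Osteoclast repressors gave 3 up and 3 down of 9 in cHet and 4 up and 1 down in cKO. Monocyte markers gave 1 and 0 rises of 11, neutrophil markers 1 up and 1 down of 16 in cHet and 0 changes in cKO, B and plasma cell markers 0 of 9 in both, mast cell markers 1 up and 1 down of 8 and 2 up and 1 down, and erythroid markers 1 and 0 rises of 8. Stromal markers gave 0 of 10 in cHet and 2 rises in cKO. T and NK cell markers had 4 tested members, too few for the list test.

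Within groups, Itgax, Mmp12 and Cd36 varied together. Itgax, an integrin of dendritic cells and macrophages, stood at 115, 37.0 and 36.2 CPM in the 3 cHet control libraries, 59.3, 137 and 132 in cHet Pg, 125, 42.4 and 45.1 in cKO control and 103, 121 and 48.0 in cKO Pg. The elastase gene Mmp12 ran from 281 to 1206 CPM over the 12 libraries and the scavenger receptor gene Cd36 from 336 to 1237 CPM, high in the same 6 libraries. These genes were chosen after their values were seen. Of 11004 genes, 729 (6.62%) followed this component with an absolute r of at least 0.9. With a term for the 2 library sets, which lowers the residual spread by construction, 675 of the 677 mean genotype calls and 99 of the 99 interaction calls were kept in the same direction.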
